A study of Mus musculus with 6 samples.

How the data were processed

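Gene expression was measured by RNA sequencing in 6 libraries of mouse OT-I CD8 T cells, 3 from cells transduced with the MigRI vector and 3 from cells transduced with Klf4. Per the labels' protocols, the cells were kept in medium with 10% serum, IL-7 and IL-15 at 5 ng/ml each and the OVA peptide at 10 ng/ml, were stimulated with the peptide every day, and were harvested on day 5. GFP-positive cells were then sorted by flow cytometry, RNA was extracted with TRI Reagent, and libraries were prepared with the TruSeq stranded mRNA kit. The labels give no batch and do not say whether the replicates came from separate animals or cultures.

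The deposited values are TPM per gene, abundances scaled by transcript length and by the total of the library, given by the authors in one file per library to 2 decimals. Per the submitters' processing notes, cutadapt 2.8, STAR 2.7.1, RSEM 1.3.1 and DESeq2 were used with the mm10 build. The annotation and the strand setting of the counting are not given in the sources used here. Each file listed 55471 entries and summed, within rounding, to the total that the unit sets. Separators inside large numbers stood in 154 to 159 values of each file and were removed, and 27 symbols that 5 files had written as dates were restored from the file that had not, in which the entries stood in the same order. A set of 113 symbols stood on more than 1 entry, 231 entries in all, and each entry was kept as its own gene, with the most abundant one standing for the symbol in lists. Positions were taken from GENCODE M21 by symbol, which matched 53388 of the 55353 different symbols.

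TPM keeps no sequencing depth and whole read counts cannot be recovered from it, so the depth of each library is unknown, no counting interval or floor is given, and the alternative of testing recovered reads with DESeq2 and edgeR could not be run. Values were transformed to log2(TPM + 1). This transformation shrinks the fold change of genes with low TPM, so that a fold change given on this scale understates the ratio of the TPM values for such genes. Genes with a TPM of at least 1 in at least 3 of the 6 libraries were tested, 11869 in all. The Klf4 group was compared with the MigRI group by limma 3.58.1 in R 4.3.3, with a linear model on group alone, moderated variances with an intensity trend (eBayes), a 2-sided test and Benjamini-Hochberg adjusted p over all genes tested. A gene was called at an adjusted p under 0.05, and counts are also given for an absolute log2 fold change of at least 1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

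The comparison, the test, the gene lists, the marker genes, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. The 26 gene lists covered the cytolytic granule and killing, effector cytokines and chemokines, inhibitory receptors, costimulatory receptors, exhaustion transcription factors, effector transcription factors, the AP-1 family, naive, memory and progenitor genes, NK-lineage receptors, trafficking and adhesion, T-cell receptor (TCR) signalling, DNA replication and S phase, mitosis, p53 targets and CDK inhibitors, apoptosis regulators, glycolysis, nuclear genes of oxidative phosphorylation, cholesterol synthesis, the amino acid starvation and ATF4 response, the interferon response, IL-2 and common gamma chain signalling, TGF-beta signalling, the KLF and SP family, reprogramming partners of KLF4, epithelial genes, and mitochondrially encoded genes. Marker genes of 8 cell types were looked up beside them. A list needed 3 tested members to be tested as a set, which left 25. Each was compared with all other tested genes by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run as alternatives. The p of fry tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. For each list the number of called members is given adjusted over all genes tested and adjusted over the list alone.

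The genes named were chosen by rule. The rule took a fixed set of 19 genes of the question (Klf4, cytolytic genes, cytokines, receptors, transcription factors and cell cycle genes), the 6 largest positive and the 6 largest negative fold changes among called genes with a mean of at least 5 TPM in the higher group, no overlap between the groups and a symbol that is not of a predicted gene, and from each list up to 3 tested members with the smallest p. It gave 96 genes. Any other list member, marker gene or family member named was chosen after its values were seen, mostly to complete a small count.

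Alternatives changed one choice at a time: a pseudocount of 0.1 or 0.5, no filter on low values, a mean TPM of at least 5, scaling by median-of-ratios factors, quantile normalization, TPM recomputed without the mitochondrially encoded genes, Klf4 and the 20 most abundant genes, a variance prior without a trend or with robust estimation, library weights, the replicate number as a block, and each library left out in turn. After seeing the data, another scaling was added in which TPM was recomputed without ribosomal protein and mitochondrially encoded genes, because their share differed between libraries. Leaving out each library in turn was also repeated, after seeing the data, with a filter of 2 libraries, because a gene found in 1 group alone cannot pass a filter of 3 libraries once that group has 2. All 10 ways to split the 6 libraries into 3 and 3 were run through the same tests. The procedure was tested on simulated data in which genes varied independently, with a spread smoothed from that of these libraries. Each run changed 50 of 11869 genes at each size, none of them at low TPM, while 3169 genes were called in the real data. At an adjusted p under 0.05 the procedure recovered 9.8% of simulated log2 changes of 0.5, 84.2% of changes of 1 and 100% of changes of 2 or 3. Of its calls 3.86% were false. These shares hold for that setting and may differ for the real comparison.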

Results

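The transcriptomes of mouse CD8 T cells were measured by RNA sequencing. The cells came from the spleen of OT-I mice, whose transgenic T-cell receptor recognises an ovalbumin peptide, and they were transduced with the retroviral vector MigRI or with Klf4, a zinc-finger transcription factor. Both groups were stimulated with the peptide every day, a treatment the labels call in vitro exhaustion, and GFP-positive cells were sorted on day 5. Each group had 3 libraries. The values are TPM, so the depth of the libraries is unknown. The libraries had 11453 to 11706 genes at 1 TPM or more. The labels do not say whether the replicates were separate animals or cultures. The p-values set the difference between groups against the spread among these libraries, and whether they hold for other animals or cultures is unknown. Levels are given as mean TPM ± SD (n = 3), and fold changes as limma estimates on the log2(TPM + 1) scale, which understates ratios for genes with low TPM.

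The comparison of Klf4 with MigRI asks how Klf4 changes gene expression in CD8 T cells under repeated stimulation, with the cytolytic effector function as the subject named in the study's title. Klf4 itself lies on chromosome 4 of mm10, from 55527143 to 55532466 on the minus strand, where GENCODE M21 annotates a protein-coding gene. Klf4 was listed at 4.10, 4.71 and 1.91 TPM in MigRI replicates 1 to 3, and at 157.60, 105.51 and 106.08 TPM in Klf4 replicates 1 to 3. The log2 fold change of Klf4 was 4.79 (SE 0.28, adjusted p = 4.17e-05). Gene-level values cannot separate transcripts of the vector from those of the cells' own Klf4 gene.

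With Klf4, 7 of 13 killing genes were higher and 3 lower, and 6 of 11 effector transcription factors were higher and 1 lower. Of 24 DNA replication genes 16 were lower and 0 higher. Of 14 naive, memory and progenitor genes 8 were lower and 3 higher, and of 15 cytokine genes 7 were higher and 3 lower. Perforin (Prf1), the pore-forming protein of the cytolytic granule, rose from 156 ± 62.4 to 1509 ± 293 TPM. Interferon gamma (Ifng) rose from 1914 ± 606 to 7697 ± 1642 TPM. Tcf7, the transcription factor of naive and progenitor T cells, fell from 80.4 ± 14.8 to 6.23 ± 2.7 TPM. The checkpoint receptor gene Pdcd1 stood at 121 ± 31.1 and 115 ± 3.97 TPM and was not called (log2 fold change -0.03, adjusted p = 0.923).

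Of 11869 genes tested, limma called 3169 at an adjusted p under 0.05, 1498 higher and 1671 lower in the Klf4 group. The change was at least 2-fold for 998 of the higher and 481 of the lower genes. A pseudocount of 0.1 gave 1058 and 633, and median-of-ratios scaling 1106 and 346. With ribosomal protein and mitochondrially encoded genes removed, a scaling chosen after seeing the data, these counts were 989 and 639. The groups did not overlap for 5355 genes, 45.1% of those tested, where chance gives 10%. The first principal component held 71.7% of the variance and separated the groups. The median log2 fold change of all tested genes was -0.14. Median-of-ratios scaling moved it to -0.01, and with it 2850 of 11861 genes were called, 1805 higher and 1045 lower, so the split into higher and lower depends on the scaling. With ribosomal protein and mitochondrially encoded genes removed, a scaling chosen after seeing the data, 1460 genes were higher and 2421 lower. The count fell by more than 1.5 times without MigRI replicate 2 (1971 genes), Klf4 replicate 2 (1664) or Klf4 replicate 3 (1771). Without Klf4 replicate 1, 606 genes rose at least 2-fold, and 906 did so when a filter of 2 libraries, chosen after seeing the data, let in genes found only in the Klf4 group.

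Klf4 replicate 1 stood apart from the other Klf4 libraries. Its correlation with them across genes was 0.968 and 0.970, against 0.989 between Klf4 replicates 2 and 3. Ribosomal protein genes held 15.9% of its TPM, against 22.3% and 21.4% in Klf4 replicates 2 and 3 and 21.6%, 21.7% and 24.7% in MigRI replicates 1 to 3. Mitochondrially encoded genes held 7.19% of its TPM, against 3.67% and 4.07% in Klf4 replicates 2 and 3. MigRI replicate 1, at 7.78%, also held more of these than MigRI replicates 2 and 3, at 5.64% and 5.62%. It correlated with MigRI replicates 2 and 3 at 0.9711 and 0.9685, against 0.9822 between MigRI replicates 2 and 3. On the second principal component, with 12.5% of the variance, MigRI replicate 1 stood at 26.76 and Klf4 replicate 1 at 26.64. The other libraries lay between -19.72 and 0.54, so part of the deviation was shared by both replicate 1 libraries.

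More killing genes rose than fell in the Klf4 group. Of 13 tested genes of the cytolytic granule and killing list, 7 rose, 3 fell and 3 were not called, and 8 rose and 3 fell adjusted over the list alone. Besides Prf1 (log2 fold change 3.35, SE 0.33, adjusted p = 0.000374), granzyme B (Gzmb), a main granule protease, rose from 4023 ± 1412 to 13259.8 ± 788 TPM. Granzyme A (Gzma) rose from 7.03 ± 7.47 to 139 ± 60.5 TPM, a log2 fold change of 4.63 (SE 0.78, adjusted p = 0.00461). Serpinb9, the inhibitor that protects a killer cell from its own granzyme B, rose by 3.14 on the log2 scale. The death ligand gene Tnfsf10 (TRAIL) fell by 1.5 on the log2 scale, and the other lower members were Lamp1 and Ctsw. As a set the list was higher than other genes (camera adjusted p = 0.0119). Its adjusted p was 0.557 with an estimated correlation. Some members of the granzyme and Serpinb9 families are close in sequence, and how reads were shared among them was not tested.

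Several abundant chemokine and cytokine genes were higher. Of 15 tested genes of effector cytokines and chemokines, 7 rose, 3 fell and 5 were not called, with the same numbers adjusted over the list alone. The chemokine gene Ccl5 rose from 32.0 ± 20.8 to 702 ± 44.8 TPM, Ccl3 by 2.55 on the log2 scale, and Csf2 (GM-CSF) from 93.2 ± 23.4 to 936 ± 273 TPM. The log2 fold change of Ifng was 2.03 (SE 0.26, adjusted p = 0.00125). The 3 lower genes were Lta, Ltb and Csf1. Tnf had a log2 fold change of -0.01 and Il2 one of -0.19, and neither was called. As a set the list just missed the threshold (camera adjusted p = 0.0501, and 0.557 with an estimated correlation). It passed with a pseudocount of 0.1 (0.0476), with a mean TPM of at least 5 (0.0346) and with ribosomal protein and mitochondrially encoded genes removed (0.0255). It also passed without MigRI replicate 2 (0.0267), MigRI replicate 3 (0.0276), Klf4 replicate 1 (0.0172) or Klf4 replicate 3 (0.0139). Its camera adjusted p was 0.262 with the most abundant genes removed, which left 12 members tested. It was 0.201 without MigRI replicate 1, 0.126 with median-of-ratios scaling and 0.101 with library weights.

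**Figure D1:**
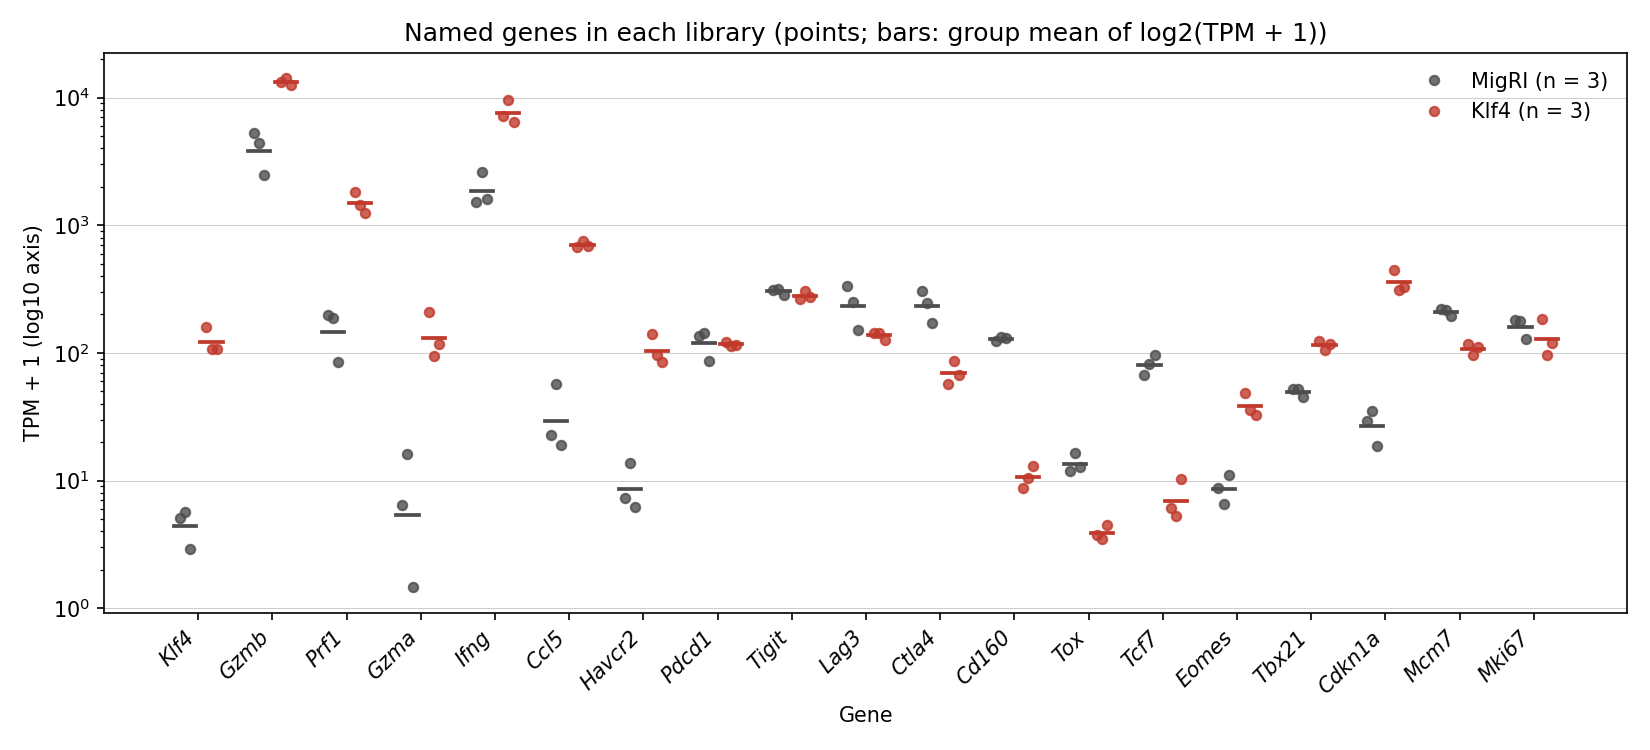
Each point is the value of a named gene in 1 library as TPM + 1 on a log10 axis, for MigRI (grey) and Klf4 (red), 3 libraries each, and bars are group means of log2(TPM + 1). Prf1 lies between 1256 and 1830 TPM in the Klf4 group and between 84.0 and 197 in the MigRI group, while the Pdcd1 values of the groups overlap.

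Inhibitory receptors split into higher, lower and uncalled genes. Of 12 tested, 3 rose, 4 fell and 5 were not called, and 3 rose and 6 fell adjusted over the list alone. Havcr2, which encodes TIM-3, rose from 8.06 ± 3.99 to 106 ± 29.4 TPM (log2 fold change 3.61, SE 0.32, adjusted p = 0.000223). Lair1 and Cd244a rose by 3.31 and 2.47 on the log2 scale. Cd160 fell from 129 ± 4.41 to 9.79 ± 2.13 TPM, Ctla4 from 239 ± 66.9 to 69.3 ± 14.5 TPM, and Btla and Cd101 also fell. Tigit had a log2 fold change of -0.12 (adjusted p = 0.505). Lag3 had one of -0.77 and missed the threshold (adjusted p = 0.0702), but passed without MigRI replicate 3 (log2 fold change -1.08, adjusted p = 0.00702), with library weights (0.022), with the replicate block (0.0341) and with ribosomal protein and mitochondrially encoded genes removed (0.0431). The set was not called (camera adjusted p = 0.917). Of 9 costimulatory receptors, 2 rose, 3 fell and 4 were not called, and 3 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.917). With any 1 library left out, 1 or 2 of them rose and 1 or 2 fell, and with no filter 1 rose and 2 fell. Tnfrsf18 (GITR) rose by 0.91 and Icos fell by 1.26 on the log2 scale. Slamf1 fell by 1.11 on the log2 scale (adjusted p = 0.0247), a call lost with no filter (0.0654) and without MigRI replicates 2 (0.0903) and 3 (0.0633) and Klf4 replicates 1 (0.0596), 2 (0.0593) and 3 (0.0713).

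More transcription factors of effector cells rose than fell. Of 11 tested effector transcription factors, 6 rose, 1 fell and 4 were not called, with the same numbers adjusted over the list alone. Tbx21, which encodes T-bet, rose from 49.0 ± 3.85 to 114 ± 10.0 TPM and Id2 from 62.3 ± 7.47 to 270.1 ± 23.2 TPM. Irf8 rose by 1.39 and Gata3, better known from helper T cells, by 2.25 on the log2 scale. The member that fell was Stat4. The set was higher than other genes (camera adjusted p = 0.00124). Its adjusted p was 0.343 with an estimated correlation.

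Of 12 exhaustion transcription factors, 2 rose, 3 fell and 7 were not called, and 2 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.67), while 5 fell with library weights. Tox, a factor of the exhausted state, fell from 12.7 ± 2.40 to 2.92 ± 0.54 TPM (log2 fold change -1.8, SE 0.19, adjusted p = 0.000537), and Ikzf2 fell by 1.96 on the log2 scale. Eomes rose from 7.77 ± 2.23 to 38.1 ± 8.68 TPM, and the other higher member was Prdm1, which the effector list also holds. The NR4A genes Nr4a1, Nr4a2 and Nr4a3 were not called, with log2 fold changes of 0.01, -0.91 and -0.23. Of 14 genes of the AP-1 family, 5 rose, 2 fell and 7 were not called, and 6 rose and 2 fell adjusted over the list alone. Jun rose by 1.82 and Junb by 0.98 on the log2 scale, and Batf2 from 0.027 ± 0.046 to 3.58 ± 0.52 TPM. Under median-of-ratios scaling 7 rose and 0 fell, and with any 1 library left out 0 or 1 fell. The AP-1 set was called higher (camera adjusted p = 0.0331, and adjusted p = 0.343 with an estimated correlation), a call lost without MigRI replicate 1 (0.0624) or Klf4 replicate 2 (0.158).

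Other KLF genes changed along with Klf4, which the KLF and SP list left out. Of 15 tested members, 6 rose, 1 fell and 8 were not called, and 6 rose and 2 fell adjusted over the list alone. With library weights 3 of them fell, and with ribosomal protein and mitochondrially encoded genes removed 2. Klf3 rose from 2.69 ± 0.12 to 106 ± 57.6 TPM, and its 3 Klf4-group values were 171.81 in replicate 1 and 66.56 and 78.53 in replicates 2 and 3. Klf11 and Klf12 rose by 2.22 and 2.09 on the log2 scale. The member that fell was Klf2, a factor of quiescent naive T cells, which went from 7.54 ± 3.91 to 0.34 ± 0.26 TPM and fails the filter when any MigRI replicate is left out. The set was called higher (camera adjusted p = 0.0172, and adjusted p = 0.557 with an estimated correlation). Among the reprogramming partners of KLF4 only Myc passed the filter. Myc fell by 0.58 on the log2 scale (adjusted p = 0.042), a call lost with median-of-ratios scaling (-0.44, adjusted p = 0.0983), with no filter (0.0824), with no intensity trend (0.0547) and without MigRI replicates 2 (0.129) and 3 (0.104) and Klf4 replicates 1 (0.0918), 2 (0.0746) and 3 (0.111).

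More genes of naive, memory and progenitor T cells fell than rose. Of 14 tested, 3 rose, 8 fell and 3 were not called, and 3 rose and 9 fell adjusted over the list alone. The lymph-node homing receptor gene Ccr7 fell from 181 ± 97.7 to 27.9 ± 9.01 TPM. Tcf7 fell by 3.54 on the log2 scale (SE 0.27, adjusted p = 0.000115), and Slamf6 also fell. S1pr1 and Foxo1 were among the members that rose. Camera did not call the set (adjusted p = 0.105), except with no filter (0.0205) and with median-of-ratios scaling (0.044).

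Of 20 tested members of the trafficking and adhesion list, 14 rose, 5 fell and 1 was not called, with the same numbers adjusted over the list alone. Itgam, an integrin chain better known from myeloid cells, rose from 0.093 ± 0.075 to 23.0 ± 7.0 TPM, the chemokine receptor gene Ccr2 from 0.14 ± 0.038 to 9.03 ± 1.47 TPM, and S1pr4 by 1.82 on the log2 scale. Ccr4, Cxcr3, Cxcr4, Itgal and Itgb1 fell. With Klf4 replicates 1, 2 or 3 left out, 9, 8 and 8 members rose, because members found only in the Klf4 group then fail the filter, and with the filter of 2 libraries 14, 13 and 13 rose. The number that fell was 3 without MigRI replicate 1, Klf4 replicate 2 or Klf4 replicate 3, and 2 without MigRI replicate 2. With a mean TPM of at least 5, 9 of 13 rose and 3 fell. The set was called higher (camera adjusted p = 4.39e-05, and adjusted p = 0.179 with an estimated correlation). Of 9 NK-lineage receptors, 2 rose, 2 fell and 5 were not called, with the same numbers adjusted over the list alone (camera adjusted p = 0.825). Klra7 rose from 0.35 ± 0.50 to 16.4 ± 4.53 TPM and Klrk1, which encodes NKG2D, fell by 1.16 on the log2 scale. Klra7 belongs to a family of closely related genes. In this list 1 fell with any 1 library left out, and 0 rose without any 1 of the Klf4 replicates, when the higher genes fail the filter (with a filter of 2 libraries 3 rose without Klf4 replicate 1 and 2 without either of the others). With no filter 3 rose and 1 fell. The median of the NK list was -0.37 on the log2 scale while its mean was 0.30 and its camera direction up.

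Signalling genes moved in both directions. Of 21 TCR signalling genes, 5 rose, 5 fell and 11 were not called, and 6 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.577). Plcg1, the phospholipase of the receptor pathway, fell from 31.7 ± 1.41 to 8.28 ± 1.59 TPM, and Cd8a and Cd3g fell by 1.05 and 0.83 on the log2 scale. The median of this list was 0.17 and its camera direction up, while its mean was -0.04. With any 1 library left out, 0 to 3 of the TCR genes rose, with median-of-ratios scaling 8 rose and 5 fell, and with no filter 2 rose and 5 fell. Of 16 genes of IL-2 and common gamma chain signalling, 5 rose, 2 fell and 9 were not called, and 5 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.097). The feedback inhibitor Socs3 rose from 6.81 ± 1.44 to 61.2 ± 11.6 TPM, Cish rose by 1.13 and the survival gene Bcl2 fell by 0.84 on the log2 scale. This set was called without Klf4 replicate 1 (0.0417) or 3 (0.0265), but not when the filter of 2 libraries was used (0.0819 and 0.0558), while 3 members rose without MigRI replicate 2, MigRI replicate 3 or Klf4 replicate 1, and 2 without Klf4 replicate 2 or 3. With the filter of 2 libraries 5 rose without Klf4 replicate 1, and with ribosomal protein and mitochondrially encoded genes removed 5 rose and 4 fell, while with no filter 2 rose and 2 fell.

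Of 11 TGF-beta signalling genes, 1 rose, 3 fell and 7 were not called, with the same numbers adjusted over the list alone (camera adjusted p = 0.989). The receptor genes Tgfbr3 and Tgfbr1 fell by 2.08 and 0.98 on the log2 scale. The inhibitor Smad7 rose by 0.88, a call lost without MigRI replicate 2 (adjusted p = 0.055) or Klf4 replicate 2 (0.0557), and 1 member fell without any 1 of the MigRI replicates (2 with the filter of 2 libraries). Of 15 interferon response genes, 2 rose, 4 fell and 9 were not called, with the same numbers adjusted over the list alone (camera adjusted p = 0.917). Ddx58, which encodes the RNA sensor RIG-I, rose by 1.61 on the log2 scale. Gbp4 rose by 0.88, a call lost without MigRI replicate 2 (0.055) or Klf4 replicate 3 (0.0511), and Irf1 fell by 0.75, a call lost without Klf4 replicate 2 (0.0743), when 1 member fell (0 with the filter of 2 libraries). With no filter 1 member of the interferon list fell.

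Genes of DNA replication were lower in the Klf4 group, and a CDK inhibitor gene was higher. Cdkn1a, which encodes the CDK inhibitor p21, rose from 26.7 ± 8.47 to 361 ± 75.6 TPM (log2 fold change 3.74, SE 0.25, adjusted p = 7.19e-05). Of 24 genes of DNA replication and S phase, 0 rose, 16 fell and 8 were not called, and 17 fell adjusted over the list alone. The helicase gene Mcm7 fell from 209 ± 13.3 to 108 ± 11.4 TPM, Mcm6 by 0.85 and E2f1 by 1.00 on the log2 scale. The set was called lower (camera adjusted p = 4.39e-05, and adjusted p = 0.504 with an estimated correlation). The number that fell was 11 with median-of-ratios scaling and 10 without Klf4 replicate 2.

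Of 24 mitosis genes tested, 0 rose, 6 fell and 18 were not called, with the same numbers adjusted over the list alone. The checkpoint kinase gene Bub1b fell by 0.71 on the log2 scale. Top2a fell by 0.61 and Ttk by 0.66, calls lost without Klf4 replicate 2 (adjusted p = 0.0646 and 0.0531). Mki67, the usual proliferation marker, stood at 161 ± 29.9 and 133 ± 45.5 TPM and was not called. The mitosis set was called lower (camera adjusted p = 0.0331, and adjusted p = 0.833 with an estimated correlation), a call lost without MigRI replicate 1 (0.0713), MigRI replicate 2 (0.078, with 3 lower) or Klf4 replicate 2 (0.199, with 1 lower).

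Of 19 p53 targets and CDK inhibitors, 5 rose, 1 fell and 13 were not called, and 5 rose and 2 fell adjusted over the list alone. Cdkn2d rose by 2.13 and the stress gene Sesn2 by 3.03 on the log2 scale. Camera did not call the set (adjusted p = 0.105), except without Klf4 replicate 3 (0.0237), where the filter of 2 libraries gave 0.0558. The number that fell was 2 without MigRI replicate 1 and 0 with any other library left out, with no filter or with median-of-ratios scaling, and it was 3 with library weights and 2 with the replicate block or with ribosomal protein and mitochondrially encoded genes removed. Of 18 apoptosis regulators, 2 rose, 4 fell and 12 were not called, and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.893). Cflar, which encodes the caspase-8 inhibitor cFLIP, rose by 1.3 and Casp8 by 0.67 on the log2 scale. The number that fell was 1 without MigRI replicate 2, Klf4 replicate 2 or Klf4 replicate 3, and 2 without MigRI replicate 3, without Klf4 replicate 1 or with median-of-ratios scaling. The median of this list was 0.035 and its camera direction up, while its mean was -0.045.

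Of 21 glycolysis genes, 0 rose, 5 fell and 16 were not called, with the same numbers adjusted over the list alone. Pdk1, which encodes a kinase that inhibits pyruvate dehydrogenase, fell from 24.3 ± 5.70 to 5.80 ± 0.49 TPM, and Pfkfb3 and Pgam1 fell by 1.54 and 0.78 on the log2 scale. The glycolysis set missed the threshold (camera adjusted p = 0.0603, and 0.833 with an estimated correlation), and passed with no filter (0.0158), with median-of-ratios scaling (0.0496) and without MigRI replicate 2 (0.0463), MigRI replicate 3 (0.00731) or Klf4 replicate 1 (0.0352). The camera adjusted p of the glycolysis set was 0.364 without MigRI replicate 1 and 0.142 without Klf4 replicate 2. Median-of-ratios scaling had 1 member higher, and 2 were higher without MigRI replicate 1. Of 25 nuclear genes of oxidative phosphorylation, limma called 0, and camera did not call the set (adjusted p = 0.563). The members with the smallest p were Sdha (log2 fold change -0.35, adjusted p = 0.0692), Ndufa4 (-1.06, 0.0785) and Atp5b (-0.32, 0.2). Sdha was called with quantile normalization (0.0398), with library weights (0.0125) and with ribosomal protein and mitochondrially encoded genes removed (0.024), and Ndufa4 with the replicate block (0.0308).

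Of 13 mitochondrially encoded genes limma called 0, and the set was not called (camera adjusted p = 0.178). Without Klf4 replicate 1, the library with the highest mitochondrial share of its group, 7 fell and the set was called lower (0.000694). With library weights 4 fell and the set was also called lower (0.0245). The gene mt-Co2 had a log2 fold change of -0.69 (adjusted p = 0.0785) and mt-Atp6 one of -0.62 (0.0847), and both were called without Klf4 replicate 1 (0.0138 and 0.0134) and with library weights (0.00429 and 0.00633), mt-Atp6 also with the replicate block (0.0178). The gene mt-Nd3 had one of -1.08 (0.13) and was called without Klf4 replicate 3 (0.0258). Of 18 cholesterol synthesis genes, 1 rose, 4 fell and 13 were not called, with the same numbers adjusted over the list alone (camera adjusted p = 0.226). Dhcr7 fell by 1.05 on the log2 scale, a call lost without MigRI replicate 2 (adjusted p = 0.0528), and Mvd rose by 0.81, a call lost without Klf4 replicate 3 (0.0631). The number that fell was 1 without MigRI replicate 2, and 2 without MigRI replicate 3, Klf4 replicate 1 or 2 or with median-of-ratios scaling, and it was 7 with library weights. Of 13 genes of the amino acid starvation and ATF4 response, 6 rose, 1 fell and 6 were not called, with the same numbers adjusted over the list alone. Besides Sesn2, the stress genes Trib3 and Chac1 rose by 2.01 and 1.8 on the log2 scale, and Atf4 had an uncalled log2 fold change of 0.34. This set was called higher (camera adjusted p = 0.0285, and adjusted p = 0.557 with an estimated correlation), a call lost with a mean TPM of at least 5 (0.125) and without MigRI replicate 1 (0.0889) or Klf4 replicate 2 (0.0524), and 3 rose without MigRI replicate 3, Klf4 replicate 2 or Klf4 replicate 3.

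Cnfn, which encodes the cornified envelope protein cornifelin, was listed at 0 in the 3 MigRI libraries and at 1156 ± 285 TPM in the Klf4 group. Nccrp1 rose from 0.057 ± 0.098 to 583 ± 490 TPM, with 1149 TPM in Klf4 replicate 1 and 301 TPM in each of the other Klf4 libraries. Serpinb9b rose from 0.32 ± 0.33 to 323 ± 48.5 TPM, Anxa8 from 0.28 ± 0.36 to 311 ± 112 TPM, AA467197 from 8.44 ± 5.73 to 1198 ± 141 TPM, and the stress gene Nupr1 from 1.33 ± 1.44 to 295 ± 68.7 TPM. Serpinb9b is close in sequence to Serpinb9, and how reads were shared between them was not tested. Of the 22 genes of the epithelial list 16 failed the filter, and of the 6 tested 5 rose and 1 was not called, and 6 rose adjusted over the list alone (camera adjusted p = 4.9e-05, and adjusted p = 0.343 with an estimated correlation). Their median was 2.64 on the log2 scale and 5.12 with a pseudocount of 0.1, while with no filter 15 were tested, 4 rose and the median was 0.76, below the 1.49 of the trafficking list. The desmosome genes Jup and Dsp rose by 6.23 and 4.73, and Epcam by 2.23, on the log2 scale. Krt19 and Cdh1 were the other higher members, and Cdh1 was not called with quantile normalization (adjusted p = 0.05). In replicates 1, 2 and 3 of the Klf4 group Jup stood at 171.70, 61.36 and 80.39 TPM, so the library that stood apart had the highest value. Only 3 members were tested, and 2 rose, when any Klf4 replicate was left out, because genes found only in the Klf4 group then fail the filter. With the filter of 2 libraries, 6 members were tested and 5 rose when any Klf4 replicate was left out.

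The largest decreases among the named genes were in Angptl2, Fgf2, Tnfsf8, Cd160, Izumo1r and Tcf7. The growth factor gene Fgf2 fell from 15.2 ± 4.89 to 0.23 ± 0.16 TPM, Tnfsf8, which encodes CD30 ligand, from 25.6 ± 10.2 to 1.07 ± 0.60 TPM, and Izumo1r, which encodes folate receptor 4, from 32.8 ± 12.9 to 1.83 ± 0.81 TPM. Angptl2 fell from 37.0 ± 39.2 to 0.56 ± 0.42 TPM, with 82.2 TPM in MigRI replicate 2 and 14 and 14.7 TPM in MigRI replicates 1 and 3. Of the 96 named genes, 21 have exons that overlap a gene on the other strand, Cd160, Tox and Cdkn1a among them, and 10 have exons that overlap another gene on the same strand. The kit keeps the strand, but the strand setting of the counting is not given in the sources used here.

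**Figure D2:**
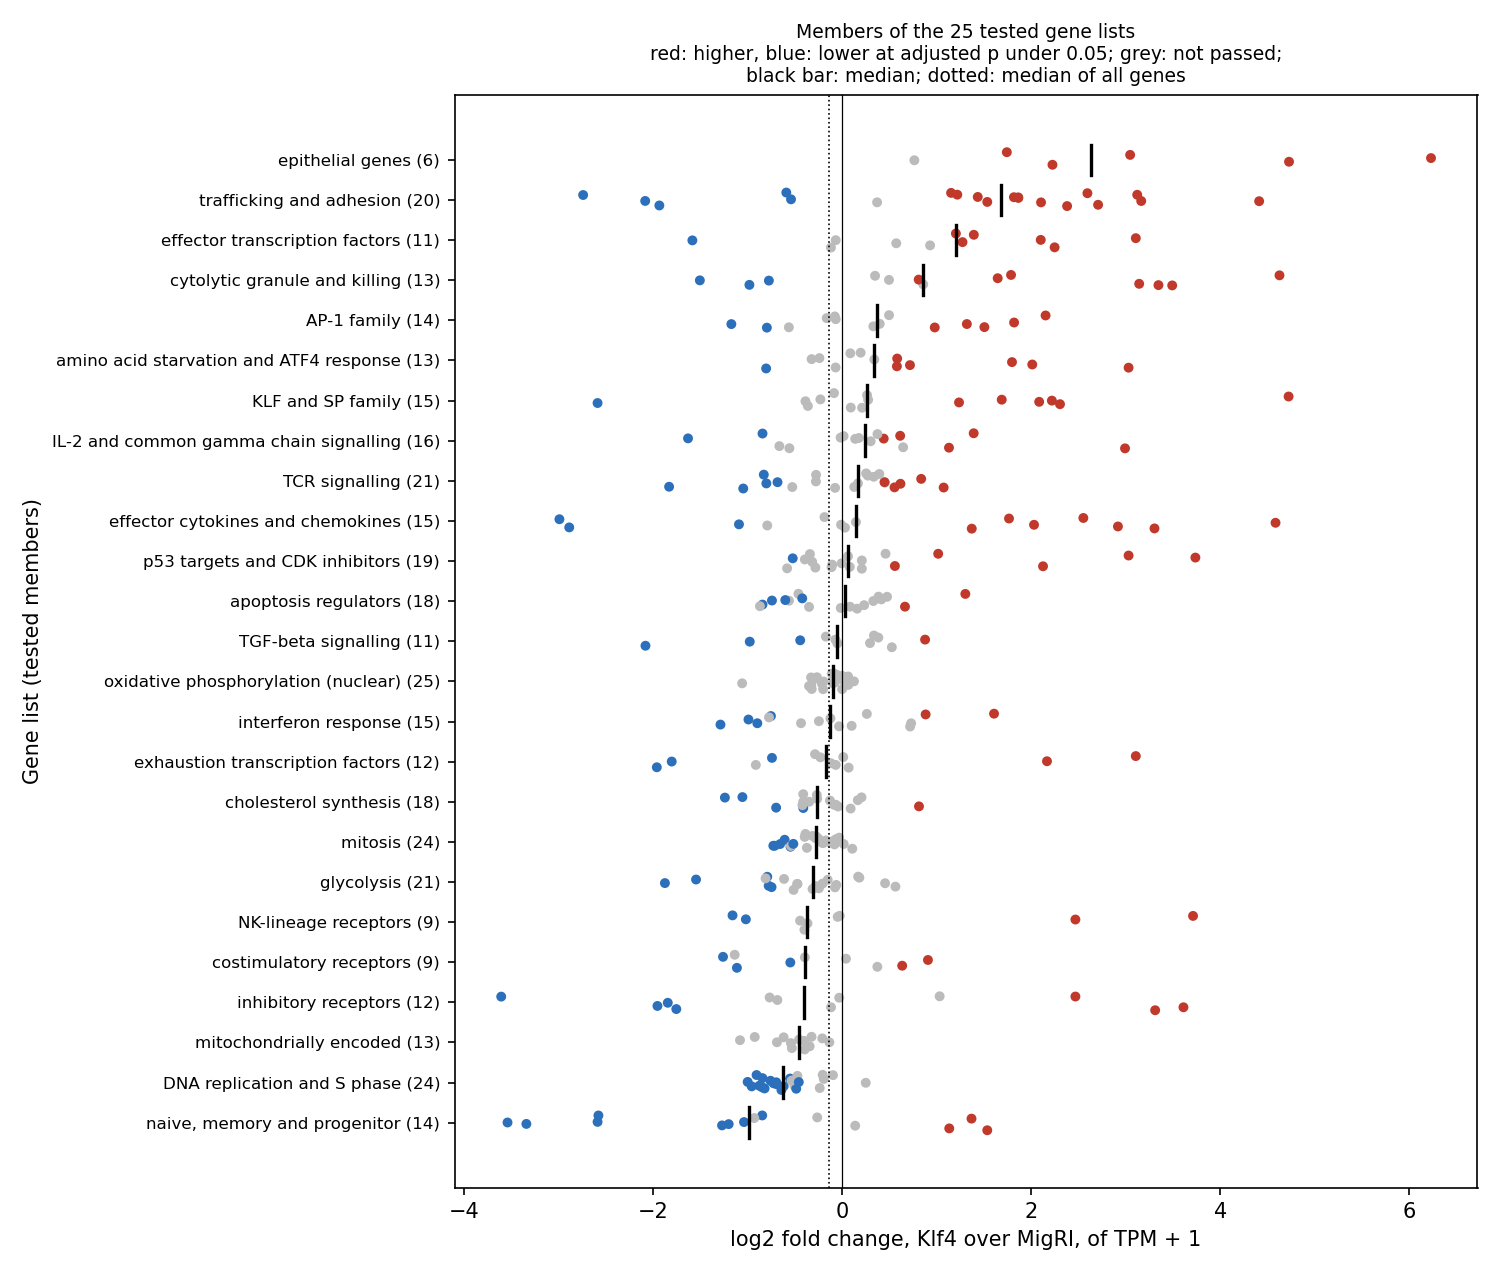
Each point is a tested member of 1 of the 25 tested gene lists, placed by its log2 fold change of TPM + 1 (Klf4 over MigRI) and coloured by its call, with the median of the list as a black bar and that of all genes, -0.14, as a dotted line. The lowest median is -0.98, for naive, memory and progenitor genes. The epithelial median of 2.64 rests on the 6 of 22 listed genes that passed the filter.

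Markers of other cell types were low or absent in both groups, with exceptions. Of the T-cell markers, Cd8a, Cd3e, Cd3g and Trbc2 fell, while Cd8b1 and Trac had uncalled log2 fold changes of 0.27 and -0.24. Cd4 averaged 0.40 and 0.19 TPM and Ncr1 0 and 0.057 TPM, in MigRI and Klf4. The macrophage genes Lyz2, Csf1r and C1qa were listed at 0 in all 6 libraries. Myeloid-associated genes that rose beside Itgam were Itgax, Cst3 (129 ± 27.3 to 387 ± 46.2 TPM), Ly6g and Mcpt8. Ly6g was listed at 0 in the MigRI group and at 14.6 ± 6.10 TPM in the Klf4 group, and Mcpt8 at 0 and at 2.14 ± 0.83 TPM. Ly6g belongs to a family of closely related genes, and Mcpt8 lies in a protease family with the granzymes. The CD4-lineage factor gene Zbtb7b rose from 4.06 ± 1.98 to 19.9 ± 0.69 TPM and the B-cell gene Cd79b from 1.47 ± 0.73 to 5.06 ± 1.92 TPM. Ighm stood at 249 ± 55.2 and 199.7 ± 16.3 TPM and was not called. Cd74, Trdc and Klri2 fell. No erythroid or platelet marker passed the filter.

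Of the 25 lists tested, camera called 9, 7 higher and 2 lower. With an estimated correlation it called 0, with a smallest adjusted p of 0.179. By fry, which asks whether the genes of a list move on balance one way, 11 lists were called. Fry did not call the killing (adjusted p = 0.0617) and mitosis (0.0875) lists, which camera had called. It called 4 lists that camera had not: naive, memory and progenitor genes (0.0114), effector cytokines and chemokines (0.0405), p53 targets and CDK inhibitors (0.0466) and cholesterol synthesis (0.0481). Camera with the preset correlation also called up to 8 lists when the 6 libraries were split into mixed groups. Each mixed group held libraries of both conditions, so part of the difference between conditions remained. These splits therefore do not show how many lists camera calls where there is no difference.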

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

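All alternatives kept Klf4 past the threshold and higher, at log2 fold changes of 4.5 to 5.14, except TPM recomputed without the most abundant genes, which leaves Klf4 out. The count of 3169 changed genes ranged from 2422 to 4545 with all 6 libraries, and from 1664 to 2967 without 1 library. With a filter of 2 libraries, chosen after seeing the data, it was 2026 without MigRI replicate 2 and 2043 without Klf4 replicate 2. Of the 3169 genes, those tested in each setting included 0 that changed direction. A fit without 1 library has fewer samples, and beyond that the cause was not tested. With the replicate number as a block 3691 genes were called. The deviations from the group means correlated at 0.22, -0.08 and 0.28 for numbers 1 to 3. MigRI replicate 1 correlated best with Klf4 replicate 1 (-0.18 and -0.15 with the others), and these stood together on the second principal component. MigRI replicate 2 also correlated best with Klf4 replicate 1 (0.13), and MigRI replicate 3 with Klf4 replicate 2 (0.29). Deviations within a group sum to 0, so these correlations are not independent, and whether equal numbers mark pairs stays open. The 9 called lists became 0 with an estimated correlation. For the trafficking and AP-1 lists that estimate was -0.02 and -0.029, below the preset 0.01, so a larger correlation does not account for the loss of their calls. For the other called lists it lay between 0.068 and 0.414. The drop to 0 calls therefore cannot be put down to correlation between genes alone, and its cause was not tested further.

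For the 96 named genes 2240 values were computed under alternatives: 2162 kept direction and side of the threshold, 43 lost the call, 18 gained it and 17 changed sign. The changes of sign were in uncalled genes. Tnf went from -0.01 to 0.13 (median-of-ratios), 0.022 (quantile) and 0.003 (most abundant genes removed), and ranged from -0.38 to 0.34 without 1 library. Il2 ranged from -0.89 to 0.48 and Pdcd1 from -0.26 to 0.11 without 1 library, and with median-of-ratios scaling Pdcd1 was 0.11 and Tigit 0.025. With the filter of 2 libraries Tnf was 0.01, 0.34 and 0.11 without MigRI replicates 2 and 3 and Klf4 replicate 1, Il2 0.48 without MigRI replicate 3, and Pdcd1 0.065 and 0.11 without MigRI replicates 1 and 2. For the 25 lists 648 values were computed: 563 were the same, 26 lost the call, 32 gained it and 27 changed the direction of the test, all in lists without a call. With the direction changed, the medians under fry were -0.40 (inhibitory receptors), 0.17 (TCR signalling) and 0.035 (apoptosis regulators). The interferon response gave -0.047 with library weights, and TGF-beta signalling -0.049 with a mean TPM of at least 5 and with the replicate block, and -0.046 with quantile normalization. For lists in which at least 1 fit without 1 library changed direction, the medians over all such fits, those that kept it included, ranged from -0.80 to -0.088 (inhibitory receptors), -0.50 to -0.34 (costimulatory receptors), -0.63 to 0 (NK-lineage receptors), -0.21 to -0.027 (oxidative phosphorylation), -0.40 to -0.075 (interferon response) and -0.22 to 0.24 (TGF-beta signalling). With the filter of 2 libraries the medians of tests that changed direction were -0.31 (inhibitory receptors) and -0.075 (interferon response) without MigRI replicate 1, -0.027 (oxidative phosphorylation) without Klf4 replicate 1, and 0.15, 0.063 and 0.056 (TGF-beta signalling) without MigRI replicate 1 and Klf4 replicates 2 and 3. The cause was not tested. Depth is unknown, so what it limits cannot be stated.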

Other observations

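Gene families were grouped by the stem of their symbols after the values were seen, and the 181 families with at least 8 tested members were compared with all other tested genes by Fisher's exact test, 2-sided, 362 tests in all. Genes of a family are not independent, so these p-values describe the data only. Of 10 annexin genes, which encode calcium-dependent membrane-binding proteins, 8 rose (adjusted p = 0.000204), Anxa1 by 5.71 and Anxa2 by 1.90 on the log2 scale. Of 17 dual-specificity phosphatase genes, only some of which are feedback regulators of MAP kinases, 9 rose and 1 fell (adjusted p = 0.00449). Dusp14 stood at 2.51 and Dusp2 at 1.5, while Dusp7 fell by 1.1 and Dusp6, at -0.6, was not called. Of 9 Gimap genes, GTPases of lymphocytes, 6 rose (adjusted p = 0.00962). Of 8 Ccl chemokine genes 5 rose and 1, Ccl20, fell (adjusted p = 0.0423). Quantile normalization gave 8, 8, 6 and 5 higher genes in these families, and median-of-ratios scaling 8, 9, 6 and 5.

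Of 10 Mcm genes, most of them parts of the replication helicase, 9 fell (adjusted p = 3.37e-05), and 8 fell with median-of-ratios scaling. Of 294 Zfp zinc-finger genes only 6 rose, fewer than among other genes (adjusted p = 2.1e-08), and 58 fell, a share not called different from that of other genes (adjusted p = 0.123). With median-of-ratios scaling 9 rose and 34 fell, and with ribosomal protein and mitochondrially encoded genes removed 6 rose and 72 fell. Of 51 genes whose symbols begin with Cd and a number, most but not all of them CD antigens, 17 rose and 12 fell (adjusted p = 0.00532 for the higher share), among them Cd70 at 3.91, Cd55 at 3.46 and Cd200 at -3.33. Of 105 Rpl genes 0 rose and 1 fell, fewer than among other genes in both directions (adjusted p = 0.000119 and 0.000245), and of 80 Rps genes 2 rose and 1 fell, fewer lower (adjusted p = 0.00615). Both stems take in genes that only share the symbol, pseudogenes among them. Ribosomal protein genes held 15.9% of the TPM of Klf4 replicate 1, against 22.3% and 21.4% in Klf4 replicates 2 and 3. Such a spread within the group makes calls harder, and how far it lowered these counts was not tested. The median of each stem was -0.21, against -0.14 for all genes. Of 15 Arhgef genes 7 rose and 3 fell (adjusted p = 0.0423 for the higher share), and 7 rose in each of the 4 other scalings. Of 34 Cep genes 2 rose and 12 fell (adjusted p = 0.0478 for the lower share), with 6 lower with median-of-ratios scaling, 9 with quantile normalization, 10 without the most abundant genes and 14 with ribosomal protein and mitochondrially encoded genes removed.

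Patterns in the epithelial genes and in the myeloid surface genes were tested with predictions written after those genes were seen to be higher. The predictions for Klf4 replicate 1 and for the splits were written before their tests were run.

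Of the 22 genes of the epithelial list 5 were called higher in the Klf4 group. Epithelial cells among the sorted cells would bring keratins, and over the 8 keratins of the list the highest value in a Klf4 library was 21.77 TPM, for Krt19, which lies between the bounds of 10 and 90 TPM. Krt5, Krt8, Krt14 and Krt18, on which the prediction was first worded, reached at most 2.29 TPM, but that choice left out Krt19, which was higher like Epcam and Cdh1, so such cells stay open, and the GFP sort would have to pass them. For scaling between libraries, the first prediction was that fewer than 5 list members would pass in some other scaling, and with quantile normalization 4 passed: Cdh1 had a log2 fold change of 1.74 (SE 0.45) before and 1.49 (SE 0.46) after, with adjusted p = 0.05, a shift smaller than its SE that ended a call near the threshold, while the other 3 scalings kept all 5. A second prediction, on scaling as the whole of the change, was worded after the first had come out this way. There the median of the 5 members was 2.845 or higher in all 4 other scalings, against the bound of 1. The 5 members had been chosen as called higher, with Krt19 in the middle at 3.048. These scalings moved the median of all genes only from -0.14 to between -0.22 and -0.01. The second test could therefore hardly have come out otherwise and decides nothing.

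The myeloid surface genes Itgam and Itgax were higher in the Klf4 group. Macrophages, monocytes or neutrophils among the sorted cells would bring their abundant transcripts, but Lyz2, Csf1r, Adgre1, C1qa, C1qb, Fcgr1, S100a8 and S100a9, chosen after the values were seen, together reached at most 0.2 TPM in a Klf4 library, against a mean of 23.0 TPM for Itgam. The outcome was thus fixed when the prediction was written, and the values show only that these 8 transcripts were nearly absent. Members of the marker lists that go the other way were Cst3, Ly6g and Mcpt8, all higher in the Klf4 group. These 8 genes do not cover basophils or dendritic cells, for which no prediction was written, but Tyrobp and Ms4a2 were listed at 0 in all 6 libraries, Fcer1g reached at most 1.44 TPM, far below Itgam, and Cd74 was lower in the Klf4 group. For Mcpt8, at a mean of 2.14 TPM, such cells stay open, as does any other source of these transcripts.

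Klf4 replicate 1 stood apart from the other Klf4 libraries. Transcript length and GC content explained 14.3% of the variance of its difference from them across genes, which lies between the bounds set for a cause and for none, with Spearman correlations of 0.37 with length and -0.11 with GC. A larger response in the library with the highest Klf4 level would make its difference from replicate 2 follow the response in replicate 3. That correlation across genes was 0.121, also between the bounds, so both stay open. Neither test covered MigRI replicate 1, which stood beside Klf4 replicate 1 on the second principal component. What the replicate 1 libraries of both groups share was not tested.

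Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, reached its count for changed genes (3169, highest other 3). The same held for genes changed at least 2-fold (1479, highest other 3) and for called lists (9, highest other 8). These 10 splits are too few for a share under 0.05. Each other split mixed the conditions, which moves their difference into the spread within groups and lowers the calls of genes. The other counts therefore do not show what would be called without a difference.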
